A study of Mus musculus with 16 samples.

How the data were processed

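RNA from mouse hearts, isolated with a fibrous tissue kit and labelled with biotin per the labels' protocols, was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array for each of 16 mice. The deposited table holds log2 values made by the authors for 35556 probe sets, with 2 decimals. The scale was read from the values: on base e the highest would be 1706580, above the 65536 of a 16-bit scanner. The submitters' processing notes name MAS5 and give no version. The quartiles of the arrays nearly coincide (25th percentile 3.73 to 3.85, 75th percentile 6.82 to 6.93), which from the values points to scaling between arrays before deposit, and which method did so is not given in the sources used here. Scaling of this kind removes any shift shared by all genes of an array.

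Groups came from the sample titles: control sham, control TAC, cKO sham and cKO TAC, 4 mice each. The labels give no batch. Each array differed from every other in at least 97.4% of probe sets, so no array is a copy of another. All mice are male per the labels, and Xist (3.27 to 3.54) and Eif2s3y (8.25 to 8.73) were checked on every array. Gene names came from the platform annotation and were set against RefSeq genes of GRCm38.p6 by Entrez ID, which matched 21698 probe sets. Of all probe sets, 21789 have 1 gene symbol, 1621 have several and 12146 are unlisted. Control probe sets were to be left out of tests by the name AFFX, but none of that name is present. Unlisted probe sets that were tested may therefore include controls. None was named from a probe set with several symbols, which left out Cdkn1a.

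Probe sets with a mean log2 value above the 40th percentile (4.37) were kept, 21333 in all. Main tests used limma 3.58.1 in R 4.3.3: a model of 4 group means on all 16 arrays (12 residual degrees of freedom), empirical Bayes with a mean-variance trend, two-sided tests, and Benjamini-Hochberg adjusted p under 0.05. The 6 comparisons were TAC against sham in each genotype, cKO against control after each surgery, cKO against control averaged over surgery, and the interaction. Fold changes are on the log2 scale with the standard error of the fit. Of 40 gene lists fixed before the data were examined, 38 had at least 5 measured members, and those for red blood cells and Schwann cells were too small to test. Lists were tested with camera at a preset inter-gene correlation of 0.01, with the probe set of highest mean per gene (13670 genes), and again with an estimated correlation and with fry. The mean of a list per array was compared between 2 groups by an exact permutation test, 4 mice against 4 (smallest possible p 0.0286). The design, the lists, the alternatives and the naming rule were fixed before the data were examined, except where stated.

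The text draws its genes from a fixed rule. The rule takes Zbtb17 and the other key genes in every comparison, the 8 largest rises and the 8 largest falls among genes past the threshold with no overlap between groups, and, where fewer than 10 pass, all that pass, filled up to 10 by the smallest p. It also takes up to 3 members of smallest p, in the direction of the list, from each called list. Genes called over a list alone, Vegfa and the other genes of TAC averaged over genotype, Myl7, Arntl, Atf3 and the genes that separate the genotypes were also chosen after their values were seen. Alternatives changed 1 choice at a time, with an exception given next: quantile normalization, median centring, no filter, a filter at the 60th percentile, no trend, only the groups compared, array weights, the replicate number as a block, the mean of a gene's probe sets, and leaving out each array. The mean of a gene's probe sets also left out probe sets without 1 gene symbol, so that 13670 genes were tested. Others were added after seeing the data: leaving out 6 arrays with Myl7 above 6, leaving out 3 sham arrays with Atf3 above 8, only probe sets with 1 gene symbol, and the count of genes with the mean of a gene's probe sets. Figures were drawn with matplotlib.

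The tests were run on simulated data made from the residuals of the 16 arrays, 10 times for each comparison, with 200 of 21333 probe sets changed. For TAC against sham in control mice, 44.3% of changes of 0.5 on the log2 scale and 89.8% of changes of 1 were recovered. For TAC against sham in cKO mice these shares were 44.0% and 89.2%, for cKO against control after sham 45.9% and 90.2%, and after TAC 49.2% and 89.4%. Averaged over surgery they were 76.6% and 96.0%, and for the interaction 12.4% and 74.2%. The changed probe sets were drawn at random, so these shares do not apply to genes of wide spread, such as Nppa, Acta1 and Postn. With no change added, the preset camera test called up to 21 of 38 lists, and camera with an estimated correlation called 0. The extracellular matrix list, shifted by 0.3, was called in 5 to 10 of 10 runs by the preset test and in 0 by the estimated one. For that list at that size, a call that did not pass with the estimated correlation therefore does not count against a change. No other list or size of shift was simulated, and fry was not run on these data. What a missed pass means for other lists or larger shifts is therefore not known. A preset call alone does not show a change either.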

Results

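Gene expression was measured in hearts of 16 male C57BL/6 mice, 1 array per mouse, in a design of 2 genotypes and 2 surgeries. Mice with a conditional knockout of Zbtb17 (cKO), the gene of the transcription factor Miz1, and control mice had transverse aortic constriction (TAC), which narrows the aorta and loads the left ventricle with pressure, or a sham operation. Mice were 8 to 10 weeks old at surgery, hearts were taken 4 weeks later, and each of the 4 groups held 4 mice. The deposited log2 values ranged from 2.34 to 14.35, and the median of an array lay between 4.85 and 4.97. Spearman correlation between arrays ranged from 0.972 to 0.987. The lowest mean correlation with its own group was that of control sham replicate 1, at 0.974. The number of arrays limits the precision of every value.

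The targeted gene was examined first. Zbtb17 (probe set 10509998) had a log2 value of 6.36 ± 0.13 in control sham, 6.45 ± 0.11 in control TAC, 6.52 ± 0.07 in cKO sham and 6.50 ± 0.02 in cKO TAC hearts (SD, n = 4 each). Averaged over surgery the cKO arrays were 0.11 ± 0.06 (SE) higher, which did not pass the test (limma, adjusted p = 0.361). The labels do not state which part of the gene was deleted, so this whole-transcript probe set does not check the genotype labels.

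Single arrays differed from others of their group. Myl7, an atrial myosin light chain, had log2 values of 6.07 to 8.83 in 6 arrays and 4.30 to 5.20 in the other 10. These 6 arrays were control sham replicate 3, control TAC replicates 1 and 2, cKO sham replicate 2 and cKO TAC replicates 1 and 2. Without them only replicates 3 and 4 remain in each TAC group. The stress-induced transcription factor gene Atf3 was at 10.18 in control sham replicate 3, 9.58 in cKO sham replicate 1 and 8.45 in control sham replicate 4, all sham arrays, while the 8 TAC arrays lay between 6.15 and 6.79. These 3 arrays also had the highest means of all 16 for the immediate early, unfolded protein response and heat shock lists, so leaving them out removes the high sham values of such genes by choice and does not test whether these differ between sham and TAC. Arntl and Dbp, core and output genes of the circadian clock, differed between mice of the same group, as in cKO sham hearts, where Dbp ranged from 7.28 to 8.42.

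**Figure D1:**
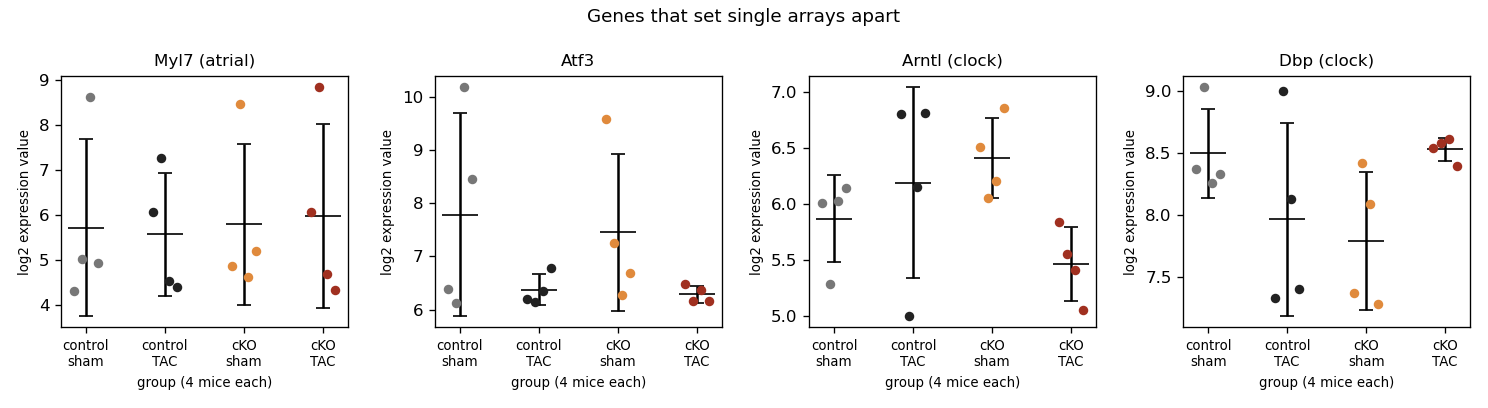
Log2 expression values of Myl7, Atf3, Arntl and Dbp (vertical axes) in the 4 groups (horizontal axis), with 1 point per mouse and the mean and SD of each group of 4. Each group holds at least 1 array with Myl7 above 6, and the 3 arrays with Atf3 above 8 are sham arrays.

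The first comparison asked what TAC changed in control hearts. No gene passed the test. The smallest adjusted p was 0.0613, for Dnah3, a dynein heavy chain gene, at 4.88 ± 0.18 after sham and 4.13 ± 0.15 after TAC (SD, n = 4 each). The next genes by p were Pde7a at a log2 fold change of -0.66 ± 0.12 (SE, adjusted p = 0.186), Slc39a1, a zinc transporter gene, at 0.43 ± 0.08, Cope, a coat protein gene of vesicle transport, at 0.31 ± 0.06, Iqca at -0.63 ± 0.13 and Cox6a1, a subunit of cytochrome c oxidase, at 0.46 ± 0.10. None of the usual markers of pressure overload passed. Nppa, which encodes atrial natriuretic peptide, had a log2 fold change of -0.13 ± 0.49, Nppb -0.29 ± 0.41, Myh7 0.50 ± 0.52, Acta1 0.57 ± 0.58, Col1a1 0.34 ± 0.25, Col3a1 0.26 ± 0.20, Postn 0.72 ± 0.64, Ccn2 -0.99 ± 0.62 and Myc -0.69 ± 0.44 (SE). Without the 6 arrays with Myl7 above 6, an alternative added after seeing the data, Nppa and Nppb took the opposite sign, at 0.53 and 0.36, as they did without control TAC replicate 1, at 0.46 and 0.095. Without the 3 sham arrays with Atf3 above 8, also added after seeing the data, Nppa was at 0.16, Nppb at 0.16, Ccn2 at 0.14 and Myc at 0.24, each of the opposite sign. These values follow a choice of arrays by a stress-induced gene. Of 21333 probe sets, limma called 0 higher and 0 lower, while 1774 had an unadjusted p under 0.05 against 1066.65 that chance gives. The count was 2 without cKO sham replicate 4, and 1 without cKO sham replicate 1, control TAC replicate 3, control TAC replicate 4 or control sham replicate 3.

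Among the gene lists, 13 of 38 passed camera with a preset correlation in control hearts, 8 higher and 5 lower after TAC. None of the 13 passed with an estimated correlation, a test that missed the extracellular matrix list, shifted by 0.3, in every simulated run. Its adjusted p was 0.857 for extracellular matrix genes and 0.803 for each of the other lists. None passed fry (smallest adjusted p = 0.721). Extracellular matrix genes were positive in 32 of 33 measured members, with a median log2 fold change of 0.20 (adjusted p = 0.00593 with the preset correlation and 0.857 with an estimated correlation). Thbs2 was at 0.42 ± 0.14 and Col6a1 at 0.39 ± 0.19 (SE), and neither passed singly. Fatty acid oxidation genes were positive in 27 of 27 members (median 0.12), and Fabp3, Slc25a20 and Acot2 passed when adjusted over the list alone. Fibroblast markers were positive in 21 of 22 members (median 0.25), with Dpep1 at 0.44 ± 0.15, and macrophage markers in 19 of 22 (median 0.24), with C1qa at 0.45 ± 0.18 and Csf1r at 0.38 ± 0.17. Interferon response genes were positive in 13 of 15, antioxidant genes in 17 of 20, ribosomal protein genes in 16 of 17 and endothelial markers in 16 of 20 members. Circadian clock genes were negative in 16 of 17 members, with Per2 at -0.60 ± 0.24. Immediate early genes were negative in 15 of 19, unfolded protein response genes in 18 of 21, heat shock protein genes in 11 of 14 and ion channel genes in 14 of 20 members. Atf3 was at -1.41 ± 0.76. Without the 3 sham arrays with Atf3 above 8, which were the highest in these lists, the immediate early, unfolded protein response and heat shock tests did not pass and had the opposite sign (adjusted p = 0.723, 0.761 and 0.0525), which the choice of arrays favours. The ion channel, endothelial and macrophage calls also ended without those 3 arrays, at medians of -0.12, 0.15 and 0.24 against -0.10, 0.11 and 0.24 with all arrays, as did the ribosomal protein call, at 0.058 against 0.12. Without the 6 arrays with Myl7 above 6, the ion channel (median -0.052), endothelial (0.13), immediate early (-0.12 against -0.21) and heat shock (-0.085 against -0.19) calls ended. Among calls that held, the median moved to 0.38 without the 6 arrays and 0.51 without the 3 for extracellular matrix genes, to 0.46 without the 6 for interferon response genes (0.22 with all arrays), and without the 3 to 0.42 for fibroblast markers and 0.20 against 0.11 for antioxidant genes. Of the 13 calls, that of extracellular matrix genes (adjusted p up to 0.147) ended without control TAC replicates 2 or 4 or control sham replicates 1 or 2. The call of ion channels (adjusted p up to 0.403) ended without cKO sham replicate 1, control TAC replicates 1 or 4 or control sham replicates 2 or 4. The calls of endothelial markers (adjusted p up to 0.437) and ribosomal proteins (adjusted p up to 0.321) ended without control TAC replicates 1 or 4 or control sham replicates 2 or 4. The call of fibroblast markers (adjusted p = 0.144) ended without control sham replicate 2. The calls of macrophage markers (adjusted p up to 0.406) and interferon response (adjusted p up to 0.643) ended without control TAC replicate 4 or control sham replicate 2. The call of unfolded protein response genes (adjusted p = 0.124) ended without control sham replicate 4. The call of immediate early genes (adjusted p = 0.108) ended without control sham replicate 3. The call of heat shock proteins (adjusted p up to 0.627) ended without cKO TAC replicate 1, control TAC replicates 1, 2 or 4 or control sham replicates 3 or 4. The call of antioxidant genes (adjusted p up to 0.162) ended without control sham replicates 1 or 2. In simulated data with no change, the preset test called a median of 11.5 lists for this comparison.

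The second comparison asked the same of cKO hearts. No gene passed. Olfr1396, an olfactory receptor gene, had the smallest p, with a log2 fold change of 1.12 ± 0.23 (SE, adjusted p = 0.595), followed by Polr3d, a subunit of RNA polymerase III, at -0.36 ± 0.07, Ttc38 at 0.81 ± 0.17, Tspan4 at 0.69 ± 0.14, Gsta3, a glutathione transferase gene, at 0.48 ± 0.11 and Epha4 at -0.73 ± 0.16. Acta1 was at 1.16 ± 0.58, Postn, a matrix protein gene, at 1.26 ± 0.64, Col3a1 at 0.41 ± 0.20 and Nppa at 0.48 ± 0.49 (SE), all with an adjusted p of at least 0.731. Myh7 was at 0.18, while Nppb was at -0.06, Ccn2 at -0.21, Myc at -0.20 and Csrp3 at -0.03. The array cKO TAC replicate 2 had the highest log2 value of all 16 arrays in Postn (11.58), Col3a1 (8.04) and Nppa (13.27). It also had the highest Myl7 (8.83), so atrial signal and a response to TAC cannot be told apart in it. The spread within the group was wide, with Acta1 at 11.69 ± 1.06 in cKO TAC hearts (SD, n = 4). limma called 0 probe sets, 1 without control sham replicate 1, and 1447 had an unadjusted p under 0.05.

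In cKO hearts 19 lists passed the preset test, 8 higher and 11 lower after TAC. None of the 19 passed with an estimated correlation, a test that missed the extracellular matrix list, shifted by 0.3, in simulated data. Its adjusted p was 0.623 for TGF-beta signalling, fatty acid oxidation, sarcomere and Z-disc, endothelial and heat shock protein genes. It was 0.616 for each of the other lists. Macrophage markers were positive in 22 of 22 members (median 0.36), interferon response genes in 15 of 15 (median 0.36) and extracellular matrix genes in 29 of 33 (median 0.36). C1qa was at 0.51 ± 0.18, Cd68 at 0.59 ± 0.21, Lum, a fibroblast marker, at 0.72 ± 0.27 and Col14a1 at 0.73 ± 0.32 (SE). Ifit2, Ifit3 and Oas1a, which are induced by interferon, passed when adjusted over the list alone. Fibroblast markers were positive in 21 of 22, smooth muscle and pericyte markers in 12 of 13, endothelial markers in 16 of 20, TGF-beta signalling genes in 10 of 17 and circadian clock genes in 13 of 17 members. Genes of the citric acid cycle were negative in 15 of 15 members (median -0.13), those of branched-chain amino acid catabolism in 17 of 17 (median -0.18) and those of oxidative phosphorylation in 26 of 32 (median -0.09). Sdha, a subunit of succinate dehydrogenase, was at -0.29 ± 0.11, Fh1 at -0.30 ± 0.11, Ppara at -0.48 ± 0.19 and Ppargc1a, a regulator of mitochondrial genes, at -0.50 ± 0.22 (SE). Also negative were fatty acid oxidation genes in 20 of 27, mitochondrial regulators in 10 of 11, sarcomere and Z-disc genes in 19 of 26, calcium handling genes in 13 of 19 and ion channel genes in 16 of 20 members. The remaining lower lists were immediate early genes (14 of 19 negative, with Dusp1 at -0.50 ± 0.15 and Jun at -0.77 ± 0.26), unfolded protein response genes (15 of 21) and heat shock protein genes (11 of 14). Of the 19 calls, those of extracellular matrix genes (adjusted p = 0.243), oxidative phosphorylation (adjusted p = 0.1003), branched-chain amino acid catabolism (adjusted p = 0.183), mitochondrial regulators (adjusted p = 0.1003) and ion channels (adjusted p = 0.370) ended without cKO TAC replicate 2. The call of TGF-beta signalling genes (adjusted p up to 0.737) ended without cKO TAC replicates 1 or 2, cKO sham replicates 3 or 4 or control sham replicate 2. The calls of fatty acid oxidation (adjusted p up to 0.981) and smooth muscle and pericyte markers (adjusted p up to 0.1003) ended without cKO TAC replicate 2 or cKO sham replicate 4, the fatty acid oxidation test turning direction without the former. The call of calcium handling (adjusted p up to 0.0758) ended without cKO TAC replicates 1 or 2 or cKO sham replicates 2 or 4. The call of sarcomere and Z-disc genes (adjusted p up to 0.243) ended without cKO TAC replicates 2 or 4 or cKO sham replicates 1, 3 or 4. The call of endothelial markers (adjusted p up to 0.458) ended without cKO TAC replicates 1 or 2 or cKO sham replicates 3 or 4. The calls of unfolded protein response genes (adjusted p = 0.168) and immediate early genes (adjusted p = 0.168) ended without cKO sham replicate 1. The call of heat shock proteins (adjusted p up to 0.423) ended without cKO TAC replicate 3 or cKO sham replicate 1. The call of circadian clock genes (adjusted p = 0.132) ended without cKO sham replicate 4. The extracellular matrix call ended without the 6 arrays with Myl7 above 6 (adjusted p = 0.668, median 0.072), as did the macrophage call (adjusted p = 0.558, median 0.060), and the tests of fatty acid oxidation (adjusted p = 0.299), TGF-beta signalling (adjusted p = 0.507), ion channels (adjusted p = 0.665) and endothelial markers (adjusted p = 0.605) also turned direction. Of the 19 calls only those of fibroblast, smooth muscle and pericyte, unfolded protein response, immediate early, heat shock, circadian clock and interferon response genes held without those 6 arrays. Among these, the median moved to 0.14 against 0.29 for fibroblast markers, 0.16 for interferon response, -0.052 against -0.16 for immediate early and -0.18 against -0.10 for unfolded protein response genes. The medians of the other lists that lost the call without turning were -0.031 for oxidative phosphorylation, -0.053 for citric acid cycle, -0.075 for branched-chain amino acid catabolism, -0.10 against -0.12 for mitochondrial regulators, -0.011 against -0.085 for calcium handling and -0.032 against -0.061 for sarcomere genes. Without the 3 sham arrays with Atf3 above 8, the calcium handling call ended at a nearly equal median of -0.086, and the sarcomere (-0.036), unfolded protein response (-0.080 against -0.10), immediate early (-0.022 against -0.16) and heat shock (-0.080 against -0.22) calls ended at smaller ones, the last 3 being lists in which those arrays were the highest. Simulated data with no change gave a median of 14 lists.

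**Figure D2:**
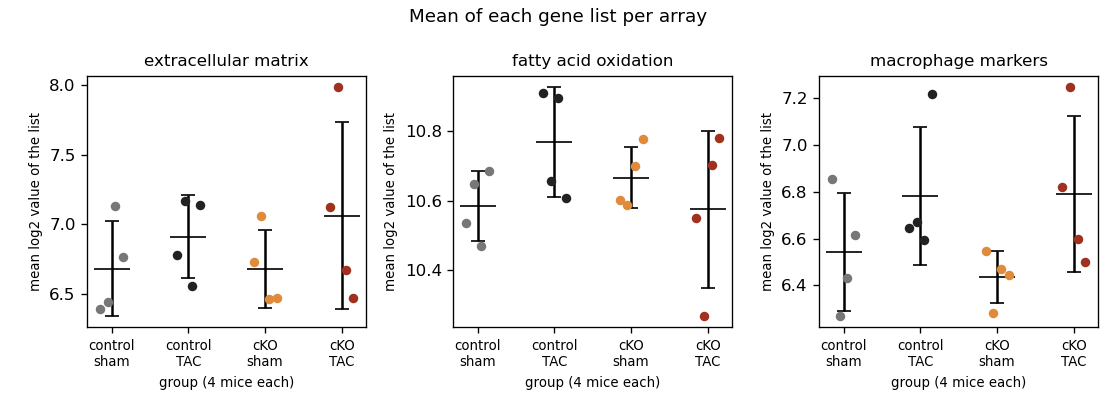
Mean log2 value of the extracellular matrix, fatty acid oxidation and macrophage lists (vertical axes) in the 4 groups (horizontal axis), with 1 point per mouse and the mean and SD of each group of 4. The extracellular matrix means were 6.68 in control sham and 6.91 in control TAC hearts, and the groups overlap. A planned exact permutation test of these means compared TAC with sham, 4 mice against 4. In the order of the lists above, its p was 0.257, 0.143 and 0.286 in control hearts. In cKO hearts its p was 0.343, 0.571 and 0.0571. Over all lists and pairwise comparisons, the smallest adjusted p of this test was 0.362.

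The third comparison set cKO against control hearts after sham surgery. Myl2 (probe set 10525343), which encodes the ventricular regulatory myosin light chain, was lower in cKO hearts, at 12.85 ± 0.03 against 13.22 ± 0.01 (SD, n = 4 each), a log2 fold change of -0.36 ± 0.06 (SE, limma adjusted p = 0.0401), with no overlap between the groups. The other 4 probe sets that passed are not listed with a gene here, may include array controls, and were chosen for naming after their values were seen. They were 10582882 at -0.80 ± 0.12, 10339648 at -0.98 ± 0.14, 10523903 at -0.65 ± 0.10 and 10341314 at 1.46 ± 0.23 (SE). C2cd5 at -0.50 ± 0.10, Ikzf2, a zinc finger transcription factor gene, at -0.66 ± 0.13, Dnah3 at -0.52 ± 0.11, Erlec1 at 0.52 ± 0.11, Dnajc13 at 0.83 ± 0.17 and Mthfd1l at -0.53 ± 0.12 (SE) did not pass (adjusted p of at least 0.209). Nppa was at 0.13 ± 0.49, Acta1 at 0.43 ± 0.58, Myh7 at 0.54 ± 0.52 and Col1a1 at 0.04 ± 0.25, and without control sham replicate 1 Nppa and Col1a1 were both at -0.064. Among cKO sham arrays, Acta1 was highest in replicate 3 (11.55, others up to 10.71) and Myh7 in replicate 2 (11.4, others up to 10.03). At an unadjusted p under 0.05, 2278 probe sets differed. The count of 5 was 27 without control sham replicate 4, 1 or 2 without cKO TAC replicate 1, cKO TAC replicate 2 or cKO sham replicate 2, and 0 without any other array except cKO TAC replicate 3. With only probe sets of 1 symbol, the count was also 0. With the mean of a gene's probe sets, 0 genes passed (Myl2 adjusted p = 0.209), and the 4 called probe sets not listed with a gene were not tested. The call of Myl2 passed under 7 of 28 alternatives, while its log2 fold change stayed between -0.38 and -0.35.

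After sham, 11 lists passed the preset test, 5 higher and 6 lower in cKO hearts. None of the 11 passed with an estimated correlation (adjusted p = 0.879 for each). That test missed the extracellular matrix list, shifted by 0.3, in simulated data. Endothelial markers were negative in 18 of 20 members (median -0.17), with Eng at -0.26 ± 0.11 and Robo4 at -0.27 ± 0.11 (SE). Sarcomere and Z-disc genes were positive in 21 of 26 members (median 0.12), with Ttn, which encodes titin, at 0.33 ± 0.13 and Myot at 0.82 ± 0.29, although Myl2, a member, was lower. Proteasome genes were positive in 21 of 22 members, with Psmd1 at 0.20 ± 0.07, branched-chain amino acid catabolism genes in 17 of 17, mitochondrial regulators in 10 of 11, with Tfb2m at 0.29 ± 0.10, and fatty acid oxidation genes in 22 of 27. Interferon response genes were negative in 13 of 15 members, with Stat2 at -0.35 ± 0.14, and cytokine and inflammation genes in 16 of 19, with Il1b at -0.34 ± 0.14. Immediate early genes were negative in 16 of 19, with Egr2 at -0.48 ± 0.16, circadian clock genes in 13 of 17, with Per2 at -0.59 ± 0.24, and ribosomal protein genes in 15 of 17 members. Of the 11 calls, that of fatty acid oxidation (adjusted p up to 0.302) ended without cKO sham replicates 3 or 4 or control sham replicates 1 or 3. The call of branched-chain amino acid catabolism (adjusted p up to 0.172) ended without cKO sham replicate 4 or control sham replicate 1. The call of mitochondrial regulators (adjusted p = 0.193) ended without control sham replicate 1. The call of sarcomere and Z-disc genes (adjusted p up to 0.202) ended without cKO sham replicate 1 or control sham replicate 1. The call of immediate early genes (adjusted p up to 0.482) ended without cKO sham replicates 3 or 4 or control sham replicates 3 or 4. The call of circadian clock genes (adjusted p up to 0.267) ended without cKO sham replicate 4 or control sham replicates 2 or 4. The call of cytokines and inflammation (adjusted p up to 0.192) ended without cKO sham replicates 3 or 4 or control sham replicates 1 or 4. The call of ribosomal proteins (adjusted p up to 0.934) ended without cKO TAC replicates 1 or 3, cKO sham replicates 1 or 3, control TAC replicates 3 or 4 or control sham replicate 1, and its test turned direction without the last. The call of proteasome genes (adjusted p = 0.0546) ended without control sham replicate 2. Simulated data with no change gave a median of 9 lists. The immediate early call ended without the 6 arrays with Myl7 above 6 (adjusted p = 0.130, median -0.033 against -0.15) and without the 3 sham arrays with Atf3 above 8 (adjusted p = 0.748, median -0.032), a list in which those arrays were the highest. Without those 3 arrays the fatty acid oxidation and circadian clock calls also ended (adjusted p = 0.148 and 0.0801), at medians of 0.097 against 0.11 and -0.32 against -0.25. Among calls that held, the median of cytokine and inflammation genes moved from -0.10 to -0.17 without the 6 and without the 3 arrays, and that of mitochondrial regulators from 0.16 to 0.25 without the 3.

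The fourth comparison set cKO against control hearts after TAC. Myl2 was again lower, at 12.76 ± 0.14 against 13.24 ± 0.02 (SD, n = 4 each), a log2 fold change of -0.48 ± 0.06 (SE, limma adjusted p = 0.00434), and it was the only probe set called. Vps28, a subunit of the ESCRT-I sorting complex, was at -0.43 ± 0.07 (adjusted p = 0.0809), Plbd1 at -0.64 ± 0.11, Slc47a1, a transporter gene, at -0.47 ± 0.09, Zfp318 at 0.43 ± 0.09, Ogfod3 at -0.34 ± 0.07, Dctn6, a dynactin subunit gene, at -0.73 ± 0.13 and C2cd5 at -0.49 ± 0.10 (SE), and none of these passed. Acta1 was at 1.02 ± 0.58 and Nppa at 0.74 ± 0.49, neither past the threshold, and without the 6 arrays with Myl7 above 6 both turned direction, at -0.12 and -0.27. The call of Myl2 ended without those 6 arrays (adjusted p = 0.357, log2 fold change -0.40), which leaves only replicates 3 and 4 of each TAC group. These changes cannot tell fewer mice from atrial signal. With the log2 fold change still at -0.48, it also ended without the 3 sham arrays with Atf3 above 8 (adjusted p = 0.0705), without the trend (adjusted p = 0.0647) and with only the 2 groups compared in the fit (adjusted p = 0.214). The count was 2 without cKO TAC replicate 1, cKO sham replicate 2, control TAC replicate 2, control TAC replicate 4 or control sham replicate 2. At an unadjusted p under 0.05, 1617 probe sets differed.

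After TAC, 8 lists passed the preset test, 3 higher and 5 lower in cKO hearts. None of the 8 passed with an estimated correlation, a test that missed the extracellular matrix list, shifted by 0.3, in simulated data. Its adjusted p was 0.723 for endothelial and circadian clock genes and 0.763 for fatty acid oxidation, sarcomere and ribosomal protein genes. It was 0.839 for stress and immediate early genes and 0.864 for oxidative phosphorylation genes. Endothelial markers were negative in 20 of 20 members (median -0.18), with Kdr, a receptor for vascular growth factor, at -0.35 ± 0.12 and Cldn5 at -0.48 ± 0.21 (SE). Cldn5 had log2 values of 7.88 and 7.51 in control TAC replicates 1 and 4, against 6.68 and 6.73 in replicates 2 and 3. Fatty acid oxidation genes were negative in 25 of 27 members (median -0.17), with Acot2 at -0.34 ± 0.13 and Ucp3 at -0.70 ± 0.29, ribosomal protein genes in 17 of 17, oxidative phosphorylation genes in 24 of 32, with Uqcrfs1 at -0.29 ± 0.09, and immediate early genes in 14 of 19, with Klf4 at -0.71 ± 0.21. Circadian clock genes were positive in 14 of 17 members (median 0.30), with Per2 at 0.66 ± 0.24, and sarcomere and Z-disc genes in 20 of 26, with Pdlim5 at 0.34 ± 0.11. Cardiomyocyte stress and fetal genes were positive in 15 of 19 members (median 0.22), with Fhl1 at 0.66 ± 0.21 and Enah at 0.54 ± 0.20. Of the 8 calls, that of cardiomyocyte stress and fetal genes (adjusted p up to 0.359) ended without cKO TAC replicate 2 or control TAC replicate 1. The call of oxidative phosphorylation genes (adjusted p = 0.779) ended without cKO TAC replicate 2. The call of sarcomere and Z-disc genes (adjusted p = 0.0661) ended without control TAC replicate 1. The call of immediate early genes (adjusted p = 0.0736) ended without control TAC replicate 4. The calls of fatty acid oxidation (adjusted p = 0.969), oxidative phosphorylation (adjusted p = 0.729) and the stress genes (adjusted p = 0.471) ended without the 6 arrays with Myl7 above 6, and the tests turned direction. Among calls that held, the median moved to -0.31 for endothelial markers, -0.27 against -0.14 for immediate early genes and 0.47 for circadian clock genes. Simulated data with no change gave a median of 10 lists.

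Averaged over surgery, with 8 cKO and 8 control arrays, 3 named genes were lower in cKO hearts. Myl2 was at a log2 fold change of -0.42 ± 0.04 (SE, limma adjusted p = 0.000232), C2cd5 (probe set 10549171), a C2 domain protein gene, at -0.50 ± 0.07 (adjusted p = 0.0345) and Vps28 (probe set 10430020) at -0.31 ± 0.05 (adjusted p = 0.0462). For each of the 3, all 8 cKO arrays lay below all 8 control arrays. The genes were picked by the test on these same arrays, so this separation is no further support. Probe set 10598085, not listed with a gene here, was higher, at 0.67 ± 0.10. Dctn6 at -0.59 ± 0.09, Gm5779 at -0.37 ± 0.06, Tecrl at 0.50 ± 0.09, Plbd1 at -0.47 ± 0.08, Ikzf2 at -0.54 ± 0.09 and Vamp4, a vesicle fusion gene from the list of genes linked to Miz1, at -0.53 ± 0.10 (SE) did not pass over all genes. Vamp4 passed when adjusted over its list alone (adjusted p = 0.00115). With the mean of a gene's probe sets, which tests 13670 genes and was counted after seeing the data, 8 genes passed: Myl2, C2cd5, Vps28, Dctn6, Gm5779, Plbd1 and Ikzf2 lower and 1700025G04Rik higher, at 0.40 (adjusted p = 0.0390). The call of Myl2 held under all 27 alternatives, that of C2cd5 under 14 and that of Vps28 under 9. At an unadjusted p under 0.05, 3182 probe sets differed. The count of 4 was 81 without control sham replicate 4, 12 without cKO TAC replicate 3, 10 without control TAC replicate 2 and 7 without control TAC replicate 3. It was 2 without cKO sham replicate 3, and 1 without cKO TAC replicates 1, 2 or 4, cKO sham replicates 1, 2 or 4, control TAC replicates 1 or 4, or control sham replicate 3.

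**Figure D3:**
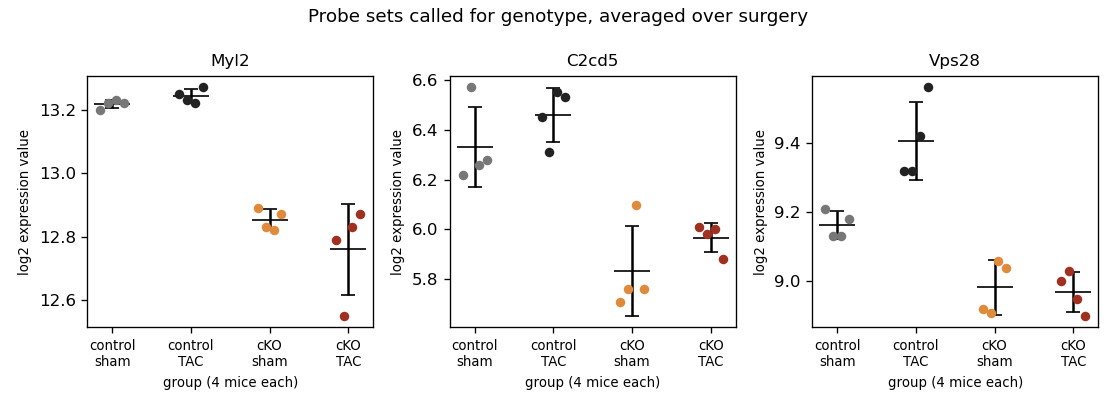
Log2 expression values of Myl2, C2cd5 and Vps28 (vertical axes) in the 4 groups (horizontal axis), with 1 point per mouse and the mean and SD of each group of 4. For each gene, the 8 cKO arrays lie below the 8 control arrays.

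In the averaged comparison 7 lists passed the preset test, 2 higher and 5 lower. None of the 7 passed with an estimated correlation, a test that missed the extracellular matrix list, shifted by 0.3, in simulated data. Its adjusted p was 0.872 for stress and interferon response genes and 0.735 for each of the other lists. Endothelial markers were negative in 20 of 20 members (median -0.18), and Eng and Robo4 passed when adjusted over the list alone. Sarcomere and Z-disc genes were positive in 21 of 26 members (median 0.085), and 7 passed when adjusted over the list alone: Myl2 lower, and Pdlim5, Mybpc3, Myot, Ttn, Actn2 and Ldb3 higher. Cardiomyocyte stress and fetal genes were positive in 16 of 19 members, with Fhl1 at 0.51 ± 0.15. Immediate early genes were negative in 17 of 19, interferon response genes in 13 of 15, cytokine and inflammation genes in 15 of 19, with Cxcl1 at -0.23 ± 0.07, and ribosomal protein genes in 16 of 17 members, with Rpl13 at -0.21 ± 0.07. Of the 7 calls, that of cardiomyocyte stress and fetal genes (adjusted p up to 0.0979) ended without cKO TAC replicate 2, cKO sham replicate 1, control TAC replicate 1 or control sham replicate 1. The call of interferon response (adjusted p up to 0.347) ended without cKO TAC replicates 3 or 4, cKO sham replicate 4, control TAC replicate 4 or control sham replicate 1. The call of cytokines and inflammation (adjusted p up to 0.158) ended without cKO TAC replicate 3, control TAC replicate 4 or control sham replicate 1. The call of ribosomal proteins (adjusted p = 0.0534) ended without control sham replicate 1. Simulated data with no change gave a median of 7 lists. The stress gene call ended without the 6 arrays with Myl7 above 6 (adjusted p = 0.122, median 0.038 against 0.20), and the immediate early (adjusted p = 0.107, median -0.11 against -0.21) and interferon (adjusted p = 0.0705, median -0.10 against -0.13) calls without the 3 sham arrays with Atf3 above 8. The interferon call held without the 6 arrays, at a median of -0.25, and the stress gene call without the 3, at 0.33.

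The interaction asked whether the response to TAC differed between the genotypes. No gene passed. Ogfod3 at -0.46 ± 0.10, Cope at -0.37 ± 0.08 and Dnah3 at 0.65 ± 0.15 (SE) had the smallest unadjusted p, followed by Usf1 at -0.51 ± 0.13, Cryzl2 at -0.72 ± 0.18 and Arsa at -0.54 ± 0.14. Nppa was at 0.61 ± 0.70, Acta1 at 0.59 ± 0.82 and Postn at 0.54 ± 0.90, and without the 6 arrays with Myl7 above 6 all 3 turned direction, at -0.47, -0.46 and -0.30. Myh7 was at -0.32, and at 0.11 without cKO sham replicate 2. Postn also turned without the 3 sham arrays with Atf3 above 8 (-0.25) and without cKO TAC replicate 2 (-0.14). limma called 0 probe sets, and 790 had an unadjusted p under 0.05, fewer than the 1066.65 that chance gives. Of the lists, 6 passed the preset test. None of the 6 passed with an estimated correlation, a test that missed the extracellular matrix list, shifted by 0.3, in simulated data. Its adjusted p was 0.628 for circadian clock genes, 0.924 for fatty acid oxidation and proteasome genes and 0.989 for each of the others. Fatty acid oxidation genes were negative in 27 of 27 members (median -0.23), and circadian clock genes were positive in 14 of 17 (median 0.49), with Per2 at 1.25 ± 0.34 and Dbp at 1.27 ± 0.46 (SE). Of the clock genes, 8 passed when adjusted over the list alone, 6 positive and 2, Arntl and Clock, negative. Oxidative phosphorylation genes were negative in 28 of 32 members, with Sdhc at -0.41 ± 0.13, branched-chain amino acid catabolism genes in 17 of 17, mitochondrial regulators in 9 of 11 and proteasome genes in 18 of 22. Of the 6 calls, that of oxidative phosphorylation genes (adjusted p = 0.195) ended without cKO TAC replicate 2. The call of branched-chain amino acid catabolism (adjusted p up to 0.698) ended without cKO TAC replicate 2, cKO sham replicate 4 or control sham replicate 1. The call of mitochondrial regulators (adjusted p up to 0.568) ended without cKO TAC replicate 2, cKO sham replicate 4, control TAC replicate 3 or control sham replicate 1. The calls of fatty acid oxidation (adjusted p = 0.165, median -0.11), oxidative phosphorylation (-0.055 against -0.10), branched-chain amino acid catabolism (-0.067 against -0.17) and mitochondrial regulators (-0.18 against -0.24) ended without the 6 arrays with Myl7 above 6, and simulated data with no change gave a median of 11.5 lists.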

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

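The tests of Myl2 against atrial tissue, cardiomyocyte content and a Cre allele, and the clock correlation, were chosen only after the result was seen. Single samples far from the other 3 of their group were searched for in 788 groups of named gene values, and 35 were found where chance gives 39.4, at 5 percent of groups, or about 1 in 20. Log2 values are given. The array cKO sham replicate 1 was high in Nppb (11.85), Hsph1 (9.02) and Robo4 (7.65) and low in Acadm (12.15) and Tsr3 (4.91). The array cKO TAC replicate 3 was high in Myo9a (7.27) and low in Dusp1 (8.64) and Stat2 (6.01). The array control sham replicate 1 was high in Uqcrfs1 (10.72) and low in Kcnd3 (6.26), Lpl (12.63), Idh3g (12.02) and Tfb2m (8.68). The array cKO TAC replicate 2 was high in Gbp3 (6.79) and low in Kcnd3 (6.19), Gsta3 (5.91) and Bckdha (8.75). The array control TAC replicate 4 was high in Csf1r (8.30) and Tnf (5.26) and low in Hsp90b1 (10.22). The array control sham replicate 3 was high in Per2 (7.17) and Pdgfrb (9.06). The array control sham replicate 2 was high in Dbp (9.03) and Fh1 (11.18) and low in Gbp3 (6.07). The array control sham replicate 4 was high in Dnajb9 (9.24) and Dnajc13 (5.52) and low in Rapgef5 (7.01). The array control TAC replicate 3 was high in Abcc9 (10.70) and Pbrm1 (8.23) and low in Sprr4 (4.48). The array cKO sham replicate 3 was high in C2cd5 (6.10) and low in Rps2 (11.61). The array cKO sham replicate 2 was high in Lrrc71 (4.79). The array control TAC replicate 1 was high in Psmb1 (8.99). Among 152 groups of list means 9 were found (7.6 by chance): glycolysis in cKO TAC replicate 2 (10.04, low), mitochondrial regulators in cKO sham replicate 3 (7.85, low), mitochondrial regulators in cKO TAC replicate 2 (7.48, low), macrophage markers in control TAC replicate 4 (7.22, high), adipocyte markers in cKO sham replicate 2 (6.82, high), atrial markers in control sham replicate 3 (7.52, high), atrial markers in cKO sham replicate 2 (7.58, high), heat shock proteins in cKO sham replicate 1 (10.5, high) and cytokines and inflammation in control TAC replicate 4 (6.37, high). Of 8 groups of array measures 1 was found (0.4 by chance), the low median log2 value of cKO TAC replicate 1, 4.85. The preset test of the interaction called 6 lists, with these median log2 differences: fatty acid oxidation -0.23, oxidative phosphorylation -0.10, branched-chain amino acid catabolism -0.17, mitochondrial regulators -0.24, circadian clock 0.49 and proteasome -0.11. Simulated data with no change gave a median of 11.5 lists, and 80 of 100 splits called as many, so these calls do not show a difference between the genotypes. None of these 6 lists passed with an estimated correlation (smallest adjusted p = 0.628), which missed the extracellular matrix list, shifted by 0.3, in simulated data.

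Myl2 was lower in all 8 cKO arrays. Atrial tissue in some samples is argued against, since without the 6 arrays with Myl7 above 6 the averaged log2 difference was still -0.37 ± 0.04 (SE). Fewer cardiomyocytes as a whole are argued against by the other 25 sarcomere genes, whose median difference was 0.086, with quartiles of 0.034 and 0.20. These genes were not chosen as particular to the ventricle, so they cannot decide on a lower share of ventricular among all cardiomyocytes. A Cre allele inserted at Myl2 may lower Myl2 itself, and cannot be told apart from an effect of Zbtb17 loss because the labels name no driver. The interaction for Myl2 was -0.12 ± 0.08 (SE), so a like difference after both surgeries, which either would give, was not excluded.

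The 12 genes that separate all cKO from all control arrays were Myl2, C2cd5, Vps28, Gm5779, Vamp4, Runx3 and Sphk1 lower, and Prob1, Esf1, Tmem167b, Vps52 and Cdc27 higher. Chance gives 2.12 such genes of 13670, and 1 of 100 splits that dealt genotype anew within each surgery gave as many, the real one, with 7 the highest of the others. Chance is therefore unlikely for the count as a whole, at this number of splits. This does not cover the genes singly, of which only Myl2, C2cd5 and Vps28 passed over all genes. A chromosome segment carried along with the targeted allele was looked for only among the 100 nearest annotated genes on each side of Zbtb17. Of the 12 genes 0 were among them, where only 58 were tested (0.051 by chance). Genes farther from Zbtb17 and the surroundings of a Cre allele were not examined, so a longer or other segment stays open. Other cell content stays open: with endothelial and atrial scores as covariates, a median share of 0.856 of the differences was left, but the lower quartile was 0.788. An effect of Zbtb17 loss, which the design names, also stays open.

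Clock genes moved apart with TAC in the 2 genotypes by the preset test, a call that did not pass with an estimated correlation (adjusted p = 0.628). The time of day at which hearts were taken is a candidate explanation that these values cannot decide. Deviations of Arntl and Dbp from their group means correlated over 16 arrays (Pearson r = -0.89, permutation p = 2e-05, and Spearman rho = -0.84, permutation p = 9e-05, 1 relation computed). Without control TAC replicate 2 and control sham replicate 2, whose Arntl deviations lay farthest from the median deviation, r was -0.77. The correlation shows that clock genes varied together between mice of the same group, whatever the source. Taking out the group means also takes out the difference between groups, so it cannot say why the genotypes moved apart. The labels give no time of day, so mice of the same group may have differed in it, and a difference between groups of this origin was not excluded.

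Other splits of the same arrays were counted for each result. For probe sets past the threshold, the splits with as many calls were 35 of 35 for TAC in control mice (real 0, highest other 73), 35 of 35 for TAC in cKO mice (real 0, highest other 0), 2 of 35 for genotype after sham (real 5, highest other 92), 3 of 35 for genotype after TAC (real 1, highest other 1), 3 of 100 for genotype averaged over surgery (real 4, highest other 7), 100 of 100 for the interaction (real 0, highest other 18) and 100 of 100 for TAC averaged over genotype (real 0, highest other 5). Where the real count is 0, every split has as many whatever the data, so those 4 comparisons say nothing about chance. Of the 3 genotype comparisons with calls, the share of such splits was smallest for the one averaged over surgery, at 3 of 100. With only 100 splits drawn and no correction for the number of results tested, chance is less likely there but not excluded. For those after sham or after TAC it is not excluded either. Splits that called 73, 92 and 18 probe sets may follow differences between arrays other than the real groups, which was not tested. For gene lists, the splits with as many calls were 6 of 35 for TAC in control mice (real 13, highest other 15), 4 of 35 for TAC in cKO mice (real 19, highest other 22), 14 of 35 for genotype after sham (real 11, highest other 19), 25 of 35 for genotype after TAC (real 8, highest other 19), 75 of 100 for genotype averaged over surgery (real 7, highest other 19), 80 of 100 for the interaction (real 6, highest other 21) and 20 of 100 for TAC averaged over genotype (real 15, highest other 20), and chance cannot be excluded for any of these counts.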

How the results depend on the processing

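The alternatives that leave out the 6 arrays with Myl7 above 6, leave out the 3 sham arrays with Atf3 above 8 or keep only probe sets with 1 gene symbol, the count of genes with the mean of a gene's probe sets, and the comparison of TAC with sham averaged over genotype, were chosen after seeing the data. The lower Myl2 averaged over surgery stayed past the threshold under 27 of 27 alternatives (log2 fold change -0.45 to -0.37, adjusted p 4.07e-06 to 0.0406). After TAC, Myl2 passed under 24 of 28 alternatives (log2 fold change -0.53 to -0.40, adjusted p 0.000326 to 0.357), and after sham under 7 of 28 alternatives (log2 fold change -0.38 to -0.35, adjusted p 0.00059 to 0.209). C2cd5 averaged over surgery passed under 14 of 27 alternatives (log2 fold change -0.55 to -0.46, adjusted p 0.00491 to 0.525), and Vps28 under 9 of 27 alternatives (log2 fold change -0.37 to -0.28, adjusted p 0.0158 to 0.505). None of the 9105 alternative values of the named genes and none of the 1843 of the called lists passed the threshold in the opposite direction, but 180 of them changed sign, and these belong to 66 results. Of 64 called lists, 18 were called in all 16 fits that left out 1 array. The number of arrays limits the precision of every value. Pseudocounts were not run because the values are already on a log2 scale, and the covariate from control probes was not run because no probe of that name is in the table. The cause of each change below was not tested, except that leaving out arrays leaves fewer mice.

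For probe sets past the threshold, the counts that moved were as follows. Without the 6 arrays with Myl7 above 6, the count was 0 against 5 for genotype after sham, 0 against 1 for genotype after TAC and 1 against 4 for genotype averaged over surgery. Without the 3 sham arrays with Atf3 above 8, the count was 0 against 5 for genotype after sham and 0 against 1 for genotype after TAC. With array weights, the count was 1 against 5 for genotype after sham and 2 against 1 for genotype after TAC. With quantile normalization, the count was 2 against 1 for genotype after TAC and 8 against 4 for genotype averaged over surgery. With median centring, the count was 1 against 0 for TAC in control mice. Without the filter, the count was 5 against 0 for TAC in control mice, 1 against 4 for genotype averaged over surgery and 1 against 0 for TAC averaged over genotype. With the stricter filter, the count was 0 against 5 for genotype after sham and 9 against 4 for genotype averaged over surgery. Without the trend, the count was 3 against 5 for genotype after sham, 0 against 1 for genotype after TAC and 2 against 4 for genotype averaged over surgery. With the replicate block, the count was 0 against 5 for genotype after sham and 2 against 4 for genotype averaged over surgery. With only probe sets of 1 symbol, the count was 1 against 0 for TAC in control mice, 0 against 5 for genotype after sham and 7 against 4 for genotype averaged over surgery. With only the 2 groups compared in the fit, the count was 1 against 0 for TAC in control mice, 1 against 0 for TAC in cKO mice, 3 against 5 for genotype after sham and 0 against 1 for genotype after TAC. With the mean of a gene's probe sets, the count of genes was 0 against 5 for genotype after sham and 8 against 4 for genotype averaged over surgery. The last of these tests 13670 genes and leaves out probe sets not listed with 1 gene. Leaving out 1 array in turn gave 0 to 2 for TAC in control mice (highest without cKO sham replicate 4), 0 to 1 for TAC in cKO mice (highest without control sham replicate 1), 0 to 27 for genotype after sham (lowest without cKO TAC replicate 4, highest without control sham replicate 4), 1 to 2 for genotype after TAC (highest without cKO TAC replicate 1), 1 to 81 for genotype averaged over surgery (lowest without cKO TAC replicate 1, highest without control sham replicate 4) and 0 to 1 for TAC averaged over genotype (highest without cKO sham replicate 4).

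No list was called with an estimated correlation or by fry in any comparison, a count of 0 against 13 for TAC in control mice, 19 for TAC in cKO mice, 11 for genotype after sham, 8 for genotype after TAC, 7 for genotype averaged over surgery, 6 for the interaction and 15 for TAC averaged over genotype. In simulated data the estimated correlation missed the extracellular matrix list, shifted by 0.3, in every run. No other list was shifted, and fry was not run on those data. Without the 6 arrays with Myl7 above 6, the count was 11 against 19 for TAC in cKO mice, 17 against 8 for genotype after TAC and 14 against 7 for genotype averaged over surgery. Without the 3 sham arrays with Atf3 above 8, the count was 7 against 13 for TAC in control mice. Leaving out 1 array in turn gave 5 to 17 for TAC in control mice (lowest without control sham replicate 2, highest without control TAC replicate 3), 9 to 21 for TAC in cKO mice (lowest without cKO TAC replicate 2, highest without cKO sham replicate 2), 5 to 13 for genotype after sham (lowest without control sham replicate 1, highest without cKO TAC replicate 2), 7 to 12 for genotype after TAC (lowest without control TAC replicate 1, highest without cKO TAC replicate 2), 3 to 11 for genotype averaged over surgery (lowest without control sham replicate 1, highest without cKO TAC replicate 2), 3 to 13 for the interaction (lowest without cKO TAC replicate 2, highest without cKO TAC replicate 4) and 10 to 18 for TAC averaged over genotype (lowest without cKO sham replicate 3, highest without cKO TAC replicate 4). The replicate block moved no list count this far. The numbers in the labels are shared by the groups, but of 24 same-numbered pairs only 6 had deviations from their group means that correlated over 0.1 (range -0.20 to 0.19), and 5 correlated best with their own number, so the samples share only a number.

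For the named genes the values are log2 fold changes. For the lists they are medians, and the sign is that of the test. The 3 arrays were chosen for high Atf3 and are all sham, so the change of sign of Atf3 and of the immediate early, unfolded protein response and heat shock values without them restates that choice and shows no dependence on processing. Without the 6 arrays with Myl7 above 6, these values took the opposite sign: for TAC in control mice, Nppa 0.53, Nppb 0.36 and Csrp3 0.04. For TAC in cKO mice, they were Zbtb17 0.03, Abcc9 0.015, TGF-beta signalling -0.067, fatty acid oxidation 0.033, ion channels -0.0025 and endothelial markers -0.013. For genotype after sham, they were Nppb 0.22, Col3a1 0.043, Ccn2 0.24, Csrp3 0.077 and Myc 0.26. For genotype after TAC, they were Nppa -0.27, Nppb -0.83, Myh7 -0.23, Acta1 -0.12, Col1a1 -0.33, Col3a1 -0.21, Postn -0.15, Ccn2 -0.24, Des -0.005, cardiomyocyte stress and fetal genes -0.12, fatty acid oxidation 0.01 and oxidative phosphorylation 0.025. For genotype averaged over surgery, they were Nppa -0.028, Nppb -0.31, Col1a1 -0.16, Col3a1 -0.083, Postn -0.0017 and Ccn2 -0.0042. For the interaction, they were Nppa -0.47, Nppb -1.05, Myh6 0.005, Acta1 -0.46, Atp2a2 0.032, Col1a1 -0.33, Col3a1 -0.25, Postn -0.30 and Ccn2 -0.48. Without the 3 sham arrays with Atf3 above 8, these values took the opposite sign: for TAC in control mice, Nppa 0.16, Nppb 0.16, Ccn2 0.14, Csrp3 0.08, Myc 0.24, Atf3 0.12, Hspa8 0.043, unfolded protein response 0.045, immediate early genes 0.05 and heat shock proteins 0.17. For TAC in cKO mice, they were Nppb 0.11, Ccn2 0.26, Csrp3 0.0058 and Myc 0.16. For genotype after sham, they were Nppb 0.25, Col3a1 0.16, Ccn2 0.44, Csrp3 0.052 and Myc 0.40. For genotype averaged over surgery, they were Csrp3 0.015. For the interaction, they were Nppb -0.052, Col1a1 -0.18, Col3a1 -0.022, Postn -0.25 and Myc -0.084. With array weights, these values took the opposite sign: for genotype after sham, Col1a1 -0.072 and Postn -0.22. For genotype after TAC, they were Col1a1 -0.080. For genotype averaged over surgery, they were Nppb -0.12, Col1a1 -0.076, Col3a1 -0.031, Ccn2 -0.22 and Myc -0.20. For the interaction, they were Col1a1 -0.0086 and Csrp3 0.019. With quantile normalization, these values took the opposite sign: for genotype after sham, Csrp3 0.011. For genotype after TAC, they were Atp2a2 -0.070 and Csrp3 0.0046. For genotype averaged over surgery, they were Atp2a2 -0.013 and Csrp3 0.0077. For TAC in control mice, leaving out 1 array in turn gave Nppa -0.56 to 0.46, Nppb -0.58 to 0.095 and Csrp3 -0.065 to 0.045. For TAC in cKO mice, leaving out 1 array in turn gave Zbtb17 -0.04 to 0.01, Nppb -0.32 to 0.26, Myh7 -0.072 to 0.61, Ccn2 -0.55 to 0.26, Csrp3 -0.07 to 0.013, Myc -0.37 to 0.16 and fatty acid oxidation -0.17 to -0.0017. For genotype after sham, leaving out 1 array in turn gave Nppa -0.064 to 0.25, Nppb -0.30 to 0.15, Col1a1 -0.10 to 0.15, Col3a1 -0.088 to 0.085, Postn -0.26 to 0.39, Ccn2 -0.69 to 0.26, Csrp3 -0.06 to 0.05, Myc -0.55 to 0.20 and ribosomal proteins -0.11 to -0.0017. For genotype after TAC, leaving out 1 array in turn gave Nppb -0.19 to 0.51, Myh6 -0.04 to 0.13, Myh7 -0.19 to 0.54, Atp2a2 -0.036 to 0.074, Col1a1 -0.18 to 0.26, Col3a1 -0.12 to 0.28, Postn -0.072 to 1.05 and Csrp3 -0.065 to 0.018. For genotype averaged over surgery, leaving out 1 array in turn gave Nppb -0.11 to 0.24, Col1a1 -0.074 to 0.15, Col3a1 -0.065 to 0.13, Postn -0.0037 to 0.56, Ccn2 -0.071 to 0.41, Csrp3 -0.041 to 0.014 and Myc -0.12 to 0.26. For the interaction, leaving out 1 array in turn gave Nppb -0.16 to 0.54, Myh7 -0.73 to 0.11, Col1a1 -0.22 to 0.22, Col3a1 -0.11 to 0.29, Postn -0.14 to 0.99 and Csrp3 -0.072 to 0.037.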

Other observations

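The comparison of TAC with sham averaged over genotype, 8 against 8 arrays, was chosen only after the result of the planned comparisons was seen. limma called 0 probe sets in it, with 2569 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0999. Olfr1396 had a log2 fold change of 0.94 ± 0.16, Xpo1, a nuclear export receptor gene, -0.31 ± 0.05, Rbm5, a splicing regulator gene, -0.40 ± 0.07 and Vegfa, a vascular growth factor gene, -0.30 ± 0.06 (SE). Extracellular matrix genes were positive in 32 of 33 members (median 0.32), fibroblast markers in 22 of 22 (median 0.27), macrophage markers in 22 of 22 (median 0.27) and interferon response genes in 14 of 15 (median 0.31). Citric acid cycle genes were positive in 0 of 15 members (median -0.08). With an estimated correlation the adjusted p was 0.655 for extracellular matrix and 0.629 for the other 4 lists. Of 38 lists, 15 passed the preset test, and in 20 of 100 splits, the real one included, at least as many did.

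Across 13670 genes, the log2 fold change of TAC in control mice correlated with that in cKO mice (Pearson r = 0.41, Spearman rho = 0.36), and the genotype difference after sham with that after TAC (r = 0.36, rho = 0.38). Each of these pairs uses different arrays on its 2 sides, and genes are not independent replicates. Among lists not called in any planned comparison, glycolysis, lymphocyte, neutrophil, adipocyte, skeletal muscle, atrial and mesothelial markers, genes linked to Miz1, autophagy and lysosome, p53 targets, apoptosis, amino acid response, cell cycle and neurohormonal lists did not pass.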
